A study of Danio rerio with 6 samples.

How the data were processed

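RNA from pooled caudal fins of zebrafish larvae at 10 days post fertilisation was compared between swim-trained and untrained larvae on 2-colour arrays, with 100 ng of RNA labelled per the labels' protocols. The labels assign trained and control RNA to Cy5 or Cy3 on each of the 6 arrays, so the direction of every ratio is known. The 6 arrays are 2 pool pairs. The arrays of one pair share their RNA, and were counted as 1 replicate. The labels give pools of the same number but do not say whether a number marks a shared clutch or day. The limma p-values from the 2 pair values therefore measure the spread between these pools. Camera p-values with a preset correlation set the genes of a list against the other genes, and do not measure that spread.

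Per the file headers and the submitters' processing notes, the authors extracted the scans with Agilent Feature Extraction 10.5.1.1. The deposited scanner files hold the raw intensity of each spot and of its local background in both channels as median pixel values, a processed intensity that was background-subtracted and dye-normalised within the array per the file headers, flags per spot, and a log10 ratio of Cy5 over Cy3. The deposited value table of the series, in log10 ratio of Cy5 over Cy3, equals the log10 ratio of the scanner files for its 43553 probes. Its column medians are 0 on each array. It is not turned to a common direction or centred across arrays, and was used only as an alternative.

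Values were computed with R 4.3.3 and limma 3.58.1, with tables handled by the R package data.table, version 1.17.8. Median spot signals and median local backgrounds were corrected with normexp at an offset of 50. On 1 array of pair 3, 18 green and 17 red local backgrounds were outliers, up to 235913 in green, and they drove the fitted normexp mean to -832.5. Local backgrounds more than 10 median absolute deviations from the median of an array were therefore replaced by that median on all arrays, after which the mean was -1.44 on that array. This step was chosen after the data had been seen, and values without it are given among the alternatives. Arrays were then normalised within each array by loess, with control spots and flagged spots at weight 0. Flagged spots were left out, and 0 spots were saturated. The offset compresses ratios of dim probes. Log2 ratios were turned to trained over control and averaged per orientation and then over both orientations of a pair, so that the dye effect cancels.

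The arrays carry 43603 probes, and spots of the same probe were averaged. The files hold no gene name column, in place of which RefSeq accessions were matched without versions to the RefSeq table of assembly GRCz12tu. This named 25173 probes with 12900 symbols. The other 18430 probes kept their own identifiers, 7832 of them Ensembl transcripts, and are counted among the genes but not named here. No coordinates were used. A probe was kept when it was well above background on every array in the control or in the trained channel. A gene was represented by its brightest kept probe, and 5558 of the tested genes had more than 1.

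Genes were tested with limma on the 2 pair values against 0, two-sided, with empirical Bayes moderation, which also gives the SE printed with each ratio, and Benjamini-Hochberg adjustment at 0.05. That leaves 1 residual degree of freedom per gene and a prior of 4.14. Genes named in the text follow a rule fixed before the data were examined. Per direction, they are the 12 genes with the largest log2 ratio among those past the threshold and of the same sign on all 6 arrays, filled up to 12 with the smallest unadjusted p among genes of that sign on all arrays, and up to 3 members of each gene list with the smallest unadjusted p. Names of clones and other placeholders were left out. Of the genes the rule picks, 1 is not reported here. The 36 gene lists, also fixed before the data were examined, were tested with camera and adjusted over the lists. They were also set against 10000 random lists of the same size matched on mean intensity in 20 bins.

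The pair values were tested on simulated data with 200 changed genes among 15773. With the spread of pool pairs 2 and 3 as measured, the trained against control test recovered 63% of 2-fold and 100% of 4-fold changes with 7 false calls. With both pairs as narrow as pair 2 it recovered 100% of both with 3 false calls. In the same 2 simulations the fit of 6 arrays with a random block made 62 and 101 false calls. The simulation gave every gene the same spread, which the real genes do not have.

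Alternatives covered background correction, offset, within-array and between-array normalisation, the deposited value table, the filter on dim probes, flagged spots, the choice of probe, technical repeats, the pair as a random block, arrays as independent, the slide as a block and within each slide, 4 pools from separate channels without pairing, an intensity trend with a robust prior, camera with an estimated correlation, and each pool pair left out. The signal over background limits dim probes, and between 54.3% and 81.2% of probes were well above background in a channel. The number of pools limits the precision.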

Results

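The series measured mRNA in caudal fins of zebrafish larvae that either swam against a current or were left untrained. Training ran from 5 to 10 days post fertilisation in sessions of 3 h, and fins were collected at 10 days. Each RNA pool came from 15 larvae. There were 2 control pools, C2 and C3, and 2 trained pools, T2 and T3. A trained pool was hybridised with the control pool of the same number on a 2-colour Agilent zebrafish array. Pool pair 2 was hybridised on 4 arrays, with both dye orientations and a technical repeat of each. Pool pair 3 was hybridised on 2 arrays, with 1 array per orientation. The replicate is therefore the pool pair, and each value below is a log2 ratio of trained over control over 2 pool pairs, with the moderated standard error (SE) that limma gives it, unless a pair is named. Moderation draws the spread of each gene towards that of all genes, so the SE is not that of the 2 pair values alone. The number of arrays and pools limits the precision. The share of probes well above background ranged from 54.3% to 81.2% across channels and arrays, and 15774 genes were tested, of which 9240 had a gene symbol.

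The comparison asked whether swim-training alters gene expression in the developing caudal fin. As groups, genes of the cell cycle, the respiratory chain, the proteasome, pigment cells, blood vessels, slow muscle and glycolysis lay lower in trained than in control fins. Each of these lists lay further below 0 in pair 3 than in pair 2. For the respiratory chain, glycolysis and the proteasome the lower level rested largely on pair 3. Their medians were -0.38, -0.22 and -0.42 there and -0.02, -0.02 and -0.05 in pair 2. Epidermal markers lay higher except with median centring in place of loess, where their median was -0.08. These 8 lists passed camera with a preset correlation, and none passed with one estimated from the data (adjusted p = 0.942 with an estimated correlation for each). The estimated version rests on the 1 residual degree of freedom of the pair values, so it could not decide whether correlation between genes explains the calls. The preset version compares genes with genes, and its p-values do not measure the spread between pools. Among 47 measured cell cycle genes the median was -0.29, with 39 below 0. No single gene passed the test over all genes. Ranks were given among genes of the same sign on all arrays whose symbol is not a clone or placeholder name. The genes ranked first were the melanosome gene pmela, with a log2 ratio of -1.58 ± 0.17 (SE), and the melanin synthesis gene tyrp1b, with a log2 ratio of -1.10 ± 0.17. On the higher side the parvalbumin gene pvalb1 of fast muscle ranked first, with a log2 ratio of 1.13 ± 0.21.

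Of the 15774 genes tested with limma, 0 were higher and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.751. At an unadjusted p under 0.05 there were 342 genes higher and 286 lower, 628 in all, where evenly spread p-values would give 789. With the sign of 1 pair swapped the same test gave 36. That is a single swap over genes that are not independent, so neither 789 nor 36 gives a firm chance level. A fit of all 6 arrays with the pool pair as a random block called 11 genes higher and 18 lower, among them pvalb1, cd9r, cfd, ifi27.1 and ifi27.2 on the higher side and pmela, tyrp1b, mia, fgfbp2b, ms4a17a.7, fads2, hist1h2a11 and tnnc2.1 on the lower side. In both pool pairs 20 genes were at least 1.5-fold higher and 31 at least 1.5-fold lower, against 8 that reached that size in opposite directions. With processed signals or the deposited table there were 103 and 85 against 39, with offset 10 there were 36 and 48 against 16, and with local backgrounds as deposited 10 and 22 against 1.

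The 12 genes of each direction with the smallest unadjusted p and the same sign on all 6 arrays are described here. They were taken from the 8722 tested genes whose symbol is not a clone or placeholder name. None of these ranked genes passed the test over all genes. Muscle genes stood on both sides. The fast muscle genes pvalb1 and tnni2a.3, a fast troponin I, had log2 ratios of 1.13 and 0.73, and the M-band gene myom1a had 0.83 ± 0.19. The troponin C gene tnnc2.1, whose namesake tnnc2 is in the fast muscle list, had -1.02 ± 0.24. The slow myosin heavy chain gene smyhc2 had -0.91 ± 0.22. The interferon-inducible genes ifi27.1 and ifi27.2 had log2 ratios of 0.89 ± 0.18 and 1.34 ± 0.32, and the latter was 3.90-fold higher in pair 2 and 1.65-fold higher in pair 3. The complement factor D gene cfd had 0.92 ± 0.20. The ictacalcin genes icn and icn2 of the epidermis had 0.80 ± 0.19 and 0.76 ± 0.18. The remaining genes on the higher side were cd9r, 2.38-fold higher in pair 2 and 1.68-fold in pair 3, the prostaglandin D2 synthase gene ptgdsb.2 at 0.71, the thymosin beta gene tmsb at 0.77 and the RNA helicase gene ddx5 at 0.82.

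On the lower side, pmela was 2.75-fold lower in pair 2 and 3.26-fold lower in pair 3, and tyrp1b was 2.15-fold and 2.14-fold lower. The genes mia and col9a1a, which encode a secreted cartilage protein and a collagen IX chain, had log2 ratios of -1.34 ± 0.23 and -0.94 ± 0.23. The values of fgfbp2b and ms4a17a.7 were -1.45 ± 0.27 and -1.27 ± 0.21. The fatty acid desaturase gene fads2 had -0.81 ± 0.17, the clusterin gene clu -0.84 ± 0.20, the histone H2A gene hist1h2a11 -0.81 ± 0.17 and the urate pathway gene uraha -0.75 ± 0.19. Of these 24 genes 16 were read by more than 1 probe, and for 1 of them, cfd, the probes had opposite signs, at -0.10 and 0.92. For 9 of the 16, cfd included, the weakest probe lay under 0.5 of the printed value, at -0.18 for pmela, 0.08 for ptgdsb.2, 0.14 for cd9r, 0.17 for myom1a, -0.33 for ms4a17a.7, -0.25 for smyhc2, 0.25 for ddx5 and -0.39 for fads2.

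**Figure D1:**
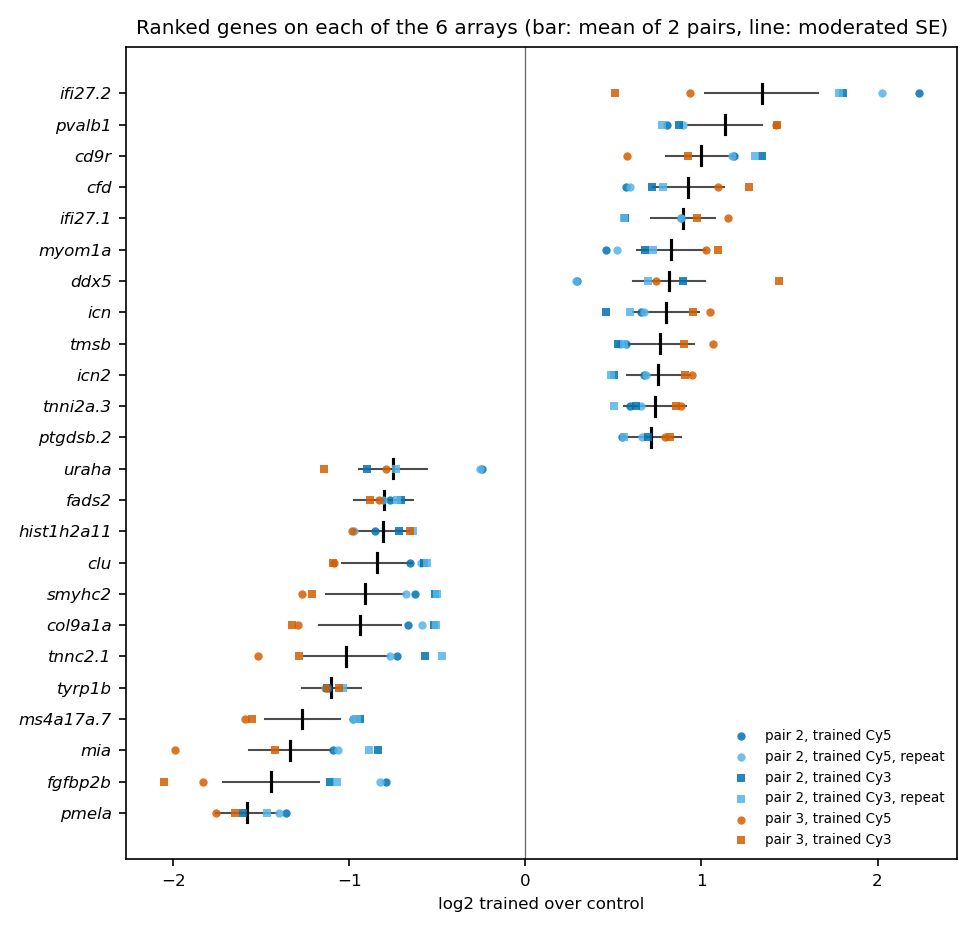
Log2 ratio of trained over control (horizontal axis) for the 24 ranked genes, with 1 point per array, coloured by pool pair and shaped by dye orientation; the bar is the mean of the 2 pool pairs and the line its moderated SE. Each gene has the same sign on all 6 arrays, from pmela at -1.58 to ifi27.2 at 1.34, and none passed the adjusted threshold.

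Of 36 gene lists fixed before the data were examined, 8 passed a camera test with a preset correlation between genes of 0.01, 7 of them lower and 1 higher in trained fins. With a correlation estimated from the data 0 lists passed, and that adjusted p of 0.942 with an estimated correlation comes from the fit of the pool pairs. This fit leaves 1 residual degree of freedom, too few to decide. For pigment cell markers the estimated correlation was 0, below the preset one, yet the unadjusted camera p went from 1.55e-06 to 0.122. Estimates for the 8 lists ran from -0.02 for epidermis to 0.49 for the proteasome list, and most lay above 0.01. No member of any list passed the test over all genes. In the lists of cell growth and energy supply, the cell cycle list lay lowest, with 36 of its 47 measured genes below 0 in both pool pairs and medians of -0.16 in pair 2 and -0.53 in pair 3. Its camera adjusted p was 1.47e-10, and the 6-array fit gave an adjusted p of 0.372 with an estimated correlation. That fit counted the 6 arrays as independent, although the arrays of a pair share their RNA. Adjusted p-values with an estimated correlation printed for single lists below come from the same fit. The replication clamp gene pcna had log2 ratios of -0.37 in pair 2 and -1.62 in pair 3, the replication protein gene rpa3 had a mean of -0.82 ± 0.26 and the spindle checkpoint gene mad2l1 -0.74 ± 0.22. The list median lay at the percentile 0 of 10000 random lists matched on intensity.

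The 57 measured genes of the TCA cycle and respiratory chain had a median of -0.22 (camera adjusted p = 1.20e-06; adjusted p = 0.611 with an estimated correlation in the 6-array fit). Their median was -0.02 in pair 2 and -0.38 in pair 3. The ATP synthase gene atp5pd had -0.95 ± 0.31 and the cytochrome c oxidase gene cox4i2 -0.62 ± 0.17, with its other probe at -0.27. Among 41 proteasome and muscle wasting genes the median was -0.22 (camera adjusted p = 1.02e-05; adjusted p = 0.611 with an estimated correlation). Their median was -0.05 in pair 2 and -0.42 in pair 3. The leading members psma6a, psmb3 and psmb6, subunits of the proteasome core, had -0.80, -0.86 and -0.67. The 31 glycolysis genes had a median of -0.14 (camera adjusted p = 0.0186; adjusted p = 0.611 with an estimated correlation), with 13 of them below 0 and 6 above 0 in both pool pairs and medians of -0.02 in pair 2 and -0.22 in pair 3. The list did not pass without the filter on dim probes (adjusted p = 0.138) or with arrays as independent (0.137). The glucose-6-phosphate isomerase genes gpia and gpib had -0.85 and -0.70, and the phosphoglycerate mutase gene pgam1a had -0.66. Within pair 2, tested on its 4 arrays against hybridisation spread with camera, 15 of the 36 lists passed. Neither the respiratory chain list (adjusted p = 0.285) nor the glycolysis list (adjusted p = 0.464) was among them, while the other 6 of the 8 lists were, with adjusted p from 3.28e-13 for the cell cycle to 0.0283 for slow muscle. The same test also passed lists that turned in pair 3, such as ribosomal protein genes (lower, adjusted p = 8.66e-11), cartilage genes (lower, adjusted p = 2.18e-08) and fast muscle genes (higher, adjusted p = 1.49e-08).

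Pigment cell markers had a median of -0.21 over 16 measured genes, 12 of them below 0 (camera adjusted p = 1.40e-05; adjusted p = 0.301 with an estimated correlation in the 6-array fit). Their median was -0.09 in pair 2 and -0.33 in pair 3. Adjusted over the list alone, pmela and tyrp1b passed, with adjusted p of 0.00373 and 0.00825 from limma, which makes 2 genes lower and 0 higher. The pteridine synthesis gene gch2, a marker of xanthophores, had -1.23 ± 0.34. Endothelial and vascular markers had a median of -0.17 over 21 genes, 17 of them below 0 (camera adjusted p = 5.09e-04; adjusted p = 0.446 with an estimated correlation). Their median was -0.07 in pair 2 and -0.30 in pair 3. The leading members were the fenestral diaphragm gene plvapb at -0.81 ± 0.24, the aquaporin gene aqp1a.1 at -0.70 ± 0.23 and the lymphatic receptor gene flt4 at -0.47 ± 0.19. Slow muscle contractile genes had a median of -0.14 over 18 genes, 16 of them below 0 (camera adjusted p = 0.00213; adjusted p = 0.446 with an estimated correlation), with tnnt1, slow troponin T, at -0.32 and mybpc1, slow myosin binding protein, at -0.31. The median of this list was -0.06 in pair 2 and -0.20 in pair 3.

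Epidermis and keratinocyte markers had a median of 0.17 over 32 genes, 24 of them above 0 (camera adjusted p = 0.0164; adjusted p = 0.301 with an estimated correlation), and the median turned to -0.08 when arrays were centred on their medians without loess. Their median was 0.17 in pair 2 and 0.23 in pair 3. Among matched random lists the median over both pairs lay at the percentile 84.03, that of pair 2 at 99.99 and that of pair 3 at 74.01. The list did not pass in 5 of 19 alternative settings, with adjusted p from 0.171 to 0.89. The keratin gene krt8 lay against the list, at -0.69 ± 0.23.

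The skeletal lists did not pass. Among 24 cartilage genes the median was 0.07, the mean was -0.03 and the test pointed lower (camera adjusted p = 0.614). The median of this list was -0.15 in pair 2 and 0.20 in pair 3. Adjusted over the list alone, mia was the 1 gene that passed, lower in trained fins (adjusted p = 0.0474 from limma), and matn3b, a matrilin of cartilage matrix, had -0.64 ± 0.17. The medians were 0.01 over 24 osteoblast and bone matrix genes, 0.08 over 8 osteoclast genes, 0.04 over 24 fin fold and actinotrichia genes and -0.09 over 22 matrix remodelling genes. In these lists the bone membrane gene ifitm5 had -0.49 ± 0.17, the osteoclast protease gene ctsk -0.84 ± 0.39, the tenascin gene tncb 1.18 ± 0.50 and the actinotrichia gene and1 0.27 ± 0.17. The values of tncb and ctsk rested on pair 3, at 2.25 against 0.10 in pair 2 for tncb and at -1.64 against -0.03 for ctsk. The other probe of tncb lay at 0.16.

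Fast muscle contractile genes had a median of 0.28 in pair 2 and -0.06 in pair 3, and a median of 0.11 over both, which turned to -0.14 with median centring in place of loess (37 genes, camera adjusted p = 0.419; 0.0316 with arrays as independent). Ribosomal protein genes had medians of -0.11 in pair 2 and 0.26 in pair 3, and a median of 0.09 over both, which turned to -0.21 with median centring and -0.10 with probes averaged (78 genes, camera adjusted p = 0.864). With these 2 settings of 19 the ribosomal list passed as lower (camera adjusted p = 2.96e-07 and 0.0368). Among the lists of response to exercise and stress, the medians were 0.01 for circadian clock genes, 0.01 for hypoxia genes, 0.01 for glucocorticoid and stress genes, -0.14 for heat shock and protein folding genes, 0.03 for immediate early genes and 0.02 for fatty acid oxidation genes, and none passed, though the heat shock list passed as lower with probes averaged and with arrays as independent (camera adjusted p = 0.00713 and 0.0316). The mitochondrial chaperonin genes hspe1 and hspd1 had -0.91 ± 0.27 and -0.59 ± 0.19, and the collagen chaperone gene serpinh1a had -0.56 ± 0.17. The early response gene klf4 had 0.78 ± 0.22 and the atrophy gene fbxo32 0.37 ± 0.17. The median was -0.04 for fatty acid and sterol synthesis genes (camera adjusted p = 0.105; 0.0112 with arrays as independent), where elovl2 and hmgcra, a fatty acid elongase and the rate-limiting enzyme of sterol synthesis, had -0.63 ± 0.17 and -0.69 ± 0.18. It was 0.01 for muscle precursor genes and 0.09 for growth hormone and IGF genes.

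Signalling lists had medians of 0.10 for Hedgehog, 0.03 for BMP and TGF-beta, -0.04 for Wnt and 0.02 for FGF and retinoic acid, and none passed. Among the members picked in these lists were the Hedgehog inhibitor gene hhip at -0.79 ± 0.30 (-0.23 in pair 2 and -1.36 in pair 3) and the BMP antagonist gene nog3 at -0.69 ± 0.24. The Wnt inhibitor gene wif1 had -0.46 ± 0.17 and ranked after dkk3b, which also lay lower. The FGF target gene etv4 had -0.58 ± 0.22. Markers of other tissues that a fin sample could hold had medians of 0.07 for neural and glial cells, -0.06 for notochord and floor plate, -0.01 for red blood cells, 0.00 for neutrophils and macrophages, 0.07 for innate immunity, -0.12 for ionocytes and mucous cells, 0.11 for gut, liver and pancreas (camera adjusted p = 0.0345 without the filter on dim probes) and 0.08 for retina and lens, and none passed. The antiviral gene mxc had 1.36 ± 0.50, made of 0.28 in pair 2 and 2.44 in pair 3, with its other probe at 0.30, and the macrophage and pigment cell gene tspan36 had -0.76 ± 0.22. Over the 28 lists that did not pass, the camera adjusted p ranged from 0.105 to 0.994, and for 11 of them the median and the direction of the test differed in sign.

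**Figure D2:**
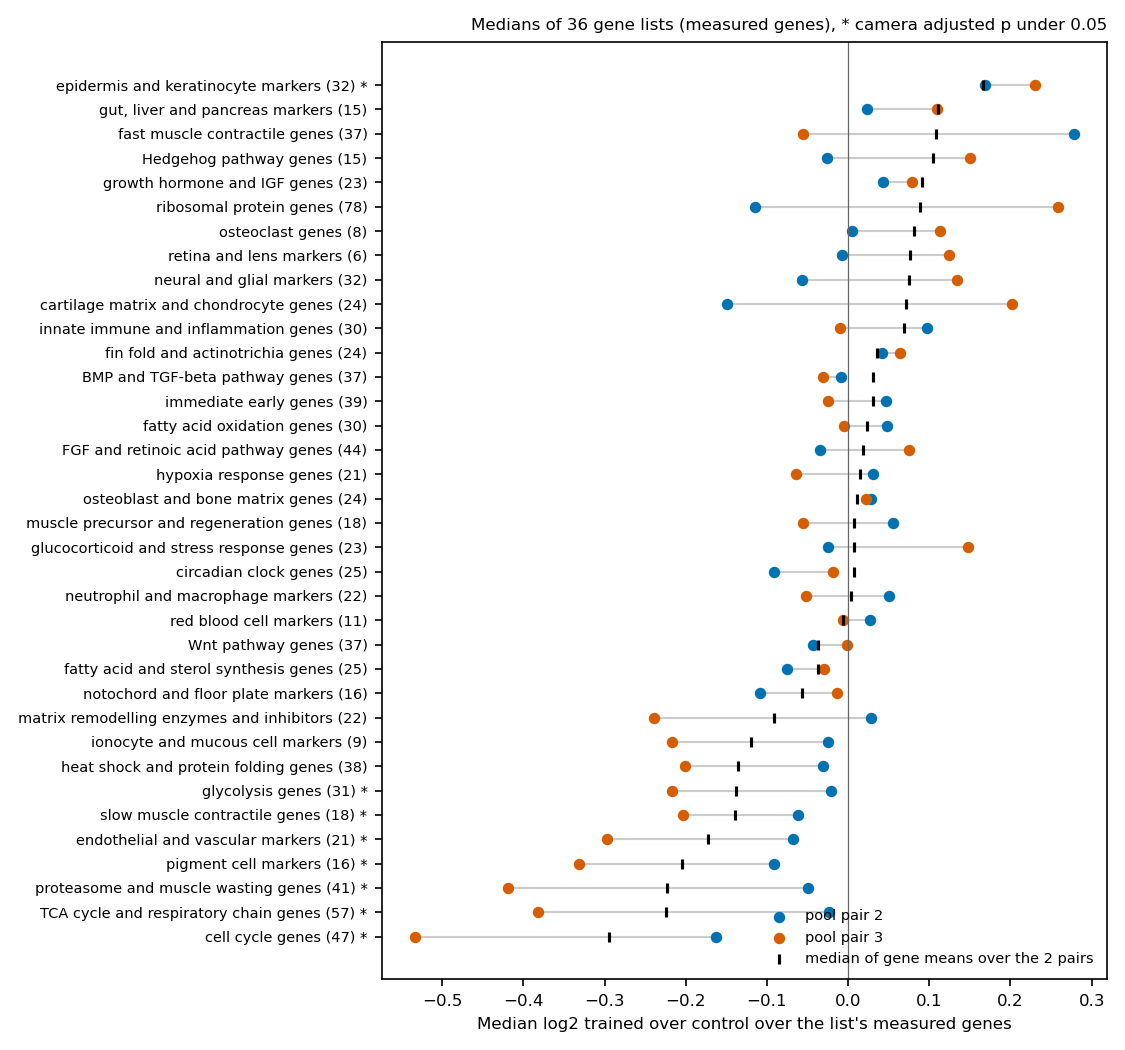
Median log2 ratio of trained over control (horizontal axis) of the 36 gene lists, with the number of measured genes in brackets, in pool pair 2, in pool pair 3 and over the gene means of both; a star marks a camera adjusted p under 0.05 with the preset correlation. Cell cycle genes lie lowest, at -0.16 and -0.53, epidermal markers lie at 0.17 and 0.23 with loess, and the medians of 16 lists have opposite signs in the 2 pairs.

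The pool pairs differed in how far trained and control fins lay apart. The SD of log2 ratios across genes was 0.15 in pair 2 and 0.53 in pair 3, and 101 genes were at least 1.5-fold apart in pair 2 against 3304 in pair 3. Across genes, which are not independent replicates, the pair values correlated with a Pearson r of 0.345 and a Spearman rho of 0.318, and 61.3% of genes had the same sign in both. The same sign on all 6 arrays was found for 1864 genes higher and 1321 lower. Technical repeats of pair 2 correlated across genes at 0.86 and 0.78, the opposite dye orientations of pair 3 at 0.889, and those of pair 2 at 0.083 to 0.158. A technical repeat kept the dye orientation of its first array, so these correlations also hold the dye effect. They do not show how far the trained over control ratio itself repeats in pair 2. The dye effect had an SD of 0.12 across genes and cancels in each pair value.

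**Figure D3:**
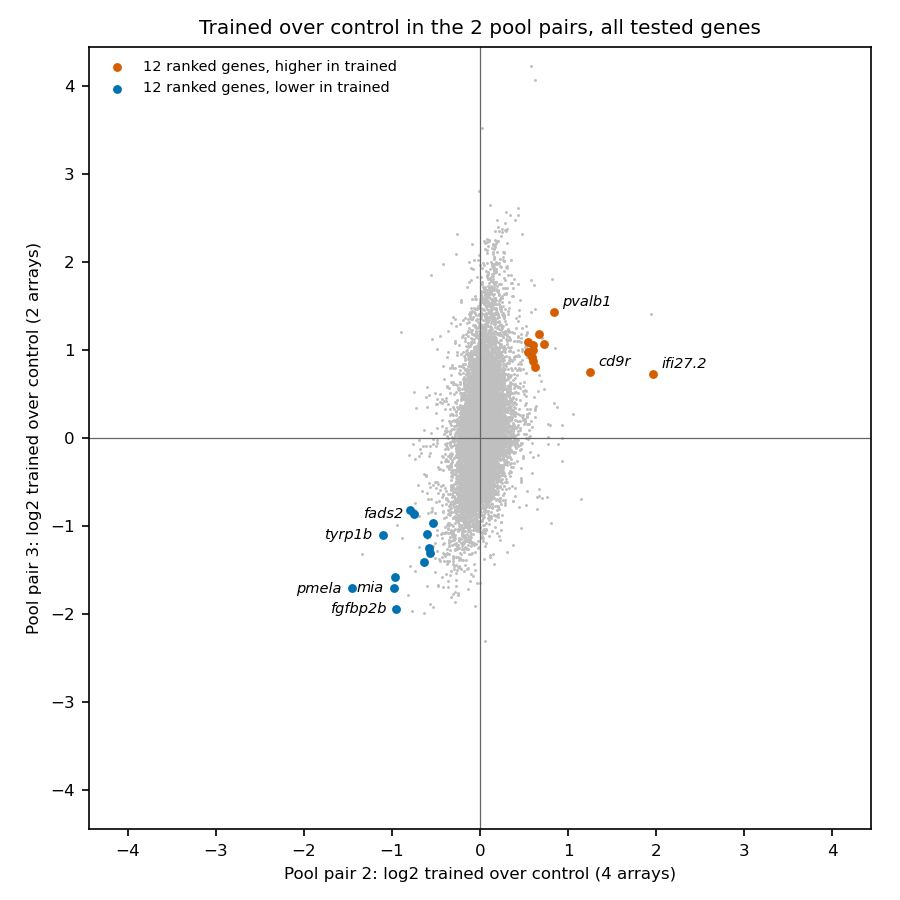
Log2 ratio of trained over control in pool pair 2 (horizontal axis) and pool pair 3 (vertical axis) for the 15774 tested genes in grey, with the 24 ranked genes in colour. The cloud is wider in pair 3 (SD 0.53) than in pair 2 (SD 0.15), and the ranked genes lie at its corners on the same side in both pairs.

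Tested against the spread between hybridisations alone, which says nothing about the spread between pools, 5165 genes differed in pair 2 and 11152 in pair 3, and of the 3980 that differed in both 75.6% had the same direction. Each slide held arrays of both pool pairs, and with the slide as a block, within slide 1 and within slide 2 there were 0 genes and 8 lists past the threshold.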

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

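All arrays measure the same contrast, so the 6 arrays were examined as 1 group for array quality, list medians and ranked genes. The tests of this part were chosen after the data had been seen. Among 65 sets of 6 arrays, 1 had an array far from the others, where 3.25 would be expected at 1 in 20 for arrays that are alike and independent. The arrays of a pair share their RNA, so that number is only a guide. A difference shared by both arrays of pair 3 is not flagged. Their SD of log2 ratios, 0.528 and 0.558 against 0.206 to 0.223 in pair 2, is such a case. The median log2 ratio of muscle precursor and regeneration genes was -0.0762 on the pair 3 array with trained RNA in Cy3 and lay between 0.0160 and 0.0645 on the other arrays.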

How the results depend on the processing

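The alternative with local backgrounds as deposited, the fits against hybridisation spread and camera within a pair were chosen after the data had been seen. Across alternatives 0 genes passed in either direction, except as follows. The random pair block gave 11 higher and 18 lower, arrays as independent 225 and 143, and the intensity trend with robust prior 1 and 6. Against hybridisation spread alone, which leaves out the spread between pools by construction, pair 2 gave 3110 and 2055, pair 3 gave 6306 and 4846, and both together 1788 and 1222. Genes at least 1.5-fold higher and lower in both pairs numbered 103 and 85 with processed signals or the deposited table, and 36 and 48 with offset 10, and 10 were higher with backgrounds as deposited; the cause was not tested. With 1 pair left out, counts at 1.5-fold ranged from 50 to 2087 higher and from 51 to 1217 lower, because the other pair alone sets them, and the test has no spread there. No list passed with an estimated correlation (0 in the pair fit and 0 in the 6-array fit), and 15 passed within pair 2. For the estimated correlation the pair fit leaves 1 residual degree of freedom, and the 6-array fit counts arrays as independent. Technical repeats, which share their dye orientation, correlated at 0.732 with processed log ratios and 0.648 without the filter on dim probes, against 0.818 on average. The cell cycle, respiratory chain, proteasome, pigment, endothelial and slow muscle lists passed in 19 of 19 alternatives of the fit and processing, glycolysis in 17 and epidermis in 14. These 19 do not include the estimated correlation and are not independent of each other. The intensity trend did not enter the list test, and between-array normalisation left the probe ratios unchanged. The deposited table repeats the processed signals. Median centring turned the epidermal median to -0.078 and the ribosomal one to -0.209, and averaging probes turned the ribosomal one to -0.103; the cause was not tested. Of 504 values of the 24 ranked genes, 0 had the other sign, and 81 of 756 list medians did. The ranked genes were picked for the same sign on all 6 arrays. Alternatives that only drop or reweight arrays could therefore not turn them, and the 2 shares cannot be compared. The numbers of the pools mark pairs hybridised together. Without the replicate block, 4 pools compared as 2 against 2 gave 0 genes higher and 0 lower, with 286 and 203 at an unadjusted p under 0.05. Deviations of same-numbered pools, which also shared their arrays, correlated at 0.187 across genes. Signal over background limits dim probes.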

Other observations

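Gene families grouped by the stem of their symbols were examined after the data had been seen, and 144 families with at least 8 tested members were tested with camera at the preset correlation. Mitochondrial ribosomal protein genes of the large subunit (mrpl) had a median log2 ratio of -0.21 over 37 genes, 26 of them below 0 in both pool pairs (adjusted p = 2.55e-05; 0.943 with an estimated correlation). Translation initiation factor genes (eif) had a median of -0.18 over 56 genes, 30 of them below 0 and 11 above 0 in both pairs (adjusted p = 4.11e-05). RNA polymerase subunit genes (polr) had -0.25 over 23 genes (adjusted p = 7.65e-05). Nucleoporin genes (nup) had -0.34 over 12 genes, 10 of them below 0 in both pairs (adjusted p = 2.77e-04). Other families passed too, among them mrps and myl, both lower (camera adjusted p = 5.99e-05 and 3.11e-04). The values rested largely on pair 3, with medians of -0.07 in pair 2 and -0.35 in pair 3 for mrpl, -0.05 and -0.32 for eif, -0.03 and -0.41 for polr, and -0.10 and -0.56 for nup. In the other direction protocadherin genes (pcdh), which encode cell adhesion proteins, had a median of 0.28 over 26 genes (adjusted p = 0.00228), made of -0.02 in pair 2 and 0.56 in pair 3. With an estimated correlation the adjusted p was 0.943 for each of these families, where 1 residual degree of freedom is too few to decide.

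All tests of the following 3 patterns were chosen after the result was seen, except the spread among bright genes and the scaling of the cell cycle list. The first pattern is the wider spread of pool pair 3. Noise of single hybridisations would make its 2 arrays, of opposite dyes on different slides, disagree, and they correlated at 0.889 across genes. Low signal would narrow the gap among bright genes, yet in the brightest 25% of genes the SD of pair 3 was 3.79 times that of pair 2. A single odd pool stays open, since the nearest distance of C3 to another pool was 1.16 times the farthest among the other 3, and 4 single pools give no spread for that ratio. Differences in tissue make-up, RNA quality or development between the pools remain open as untested, and training may also act unequally between pools.

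The second pattern is the lower level of cell cycle genes. Over 8 scaling and background settings the list median minus the median of all genes was at most -0.242. The lower level was not confined to pool pair 3, since the median in pair 2 was -0.163 (95% bootstrap interval over genes -0.202 to -0.119). That interval holds no spread between pools. A chance difference between single pools stays open, since pair 2 is 1 pool per group, 0.0571 of the other 35 lists had a pair 2 median as far from 0, though none as low, and ribosomal and cartilage genes lay lower in pair 2 but higher in pair 3. Epidermal markers lay higher, at a median of 0.166. Dilution by epidermal RNA would lower markers of other tissues as far as the cell cycle list at -0.294. The joint median of neural, notochord, red blood cell and leukocyte markers was 0.00833 (interval -0.0573 to 0.0752). Pigment, endothelial and slow muscle lists lay lower, at -0.205, -0.172 and -0.139, and fast muscle and cartilage lists higher, at 0.108 and 0.0707. The fall was thus not shared by all other tissues, but a rise in some of them could mask dilution by epidermal RNA. That explanation therefore stays open. Dilution by neural, notochord, red blood cell or leukocyte RNA also stays open, since the highest of their list medians was 0.0746. A lower share of dividing cells in trained fins may account for the pattern but was not tested, nor was RNA quality.

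The third pattern is the lower level of pigment markers. A loss of melanophores alone would leave xanthophore and iridophore genes at 0 or higher. Their median over 7 genes was -0.0886 (interval -0.575 to 0.0441), against -0.369 over 6 melanophore genes. The 7 were gch2, pts, pax7a, gart, paics, slc2a15b and csf1ra. Of these, csf1ra is also in the macrophage list and pax7a in the muscle precursor list. The 2 readings cannot be told apart with so few genes, not all particular to these cells. The position of the tail cut stays open, since the joint median of fast muscle and neural markers, 0.0952, mixes lists that lay on opposite sides of 0 in each pair. The lower level was not confined to pool pair 3, since the median in pair 2 was -0.0911 (interval -0.351 to -0.0316). This interval too is over genes and holds no spread between pools. A chance difference between single pools stays open here too, with 0.229 of the other 35 lists as far from 0 in pair 2. A change in pigment cell number or in pigment gene expression may explain it, and which of them is open.

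The 4 pools allow 3 splits, the real one included, which is too few for a share under 0.05. The real split gave 0 genes at an adjusted p under 0.05 and the highest other 0. At an unadjusted p under 0.05 the real split gave 489 genes, the split of pools numbered 2 against 3 gave 1577 and the remaining split 36. The pools of the same number were the closest for C2 and T2 (SD of the difference 0.152) and the farthest apart for C3 and T3 (0.528), with pools of different number in between (0.348 to 0.472). Pools of different number never shared an array. Differences between arrays therefore enter their distances and the split of pools numbered 2 against 3, but cancel between pools of the same number. These counts and distances are thus not like for like.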
